A study of Mus musculus with 12 samples.

How the data were processed

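RNA was measured in 12 libraries of mouse colon, 5 from control and 7 from ablated animals, taken as full-thickness pieces at the inked injection site. Per the labels, polyadenylated RNA was extracted with Trizol and made into stranded libraries. Per the submitters' processing notes, reads were separated with bcl2fastq 2.17, aligned with HISAT to mm10 and counted per gene with featureCounts; no version is given for the last 3. The deposited files hold TPM per gene, a length-scaled share of each library, as per-sample files and as a series table, and the values of the 12 per-sample files are identical to those of the table. The series file also holds the authors' deposited table of an edgeR comparison between the groups, with log2 fold change, mean log2 CPM, a score (the F statistic), p-value and false discovery rate per gene; its version, design and filter are not stated. These are used only as a comparison at the end of the report.

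The table holds 27179 genes, of which 1275 have no symbol and 4337 are 0 in all libraries. Gene IDs and symbols were those of the files, and coordinates on mm10 came from GENCODE for 24021 genes matched by Ensembl ID. Pairwise Pearson r of log2 values between libraries was 0.951 to 0.993, and no library or column was left out.

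The unit was TPM, so the count test planned for raw counts was not run. Whole reads were recovered from the TPM all the same, to state depth: for each gene a length of 20 to 30000 bases was searched that makes the values of all libraries whole multiples of each library's unit. Such a length was found for 22840 of 22842 genes above 0, 99.99% of values lay within 0.05 read of a whole number, and the recovered mean log2 CPM had r = 0.999 with those of the authors. Depth was 13.4 to 26.9 M recovered reads. At that depth 1 read per kilobase of transcript is worth 0.0697 to 0.129 TPM, so genes near the minimum rest on few reads.

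Genes with at least 0.5 TPM in at least 5 libraries were tested, 16164 in all. Each was fitted on log2(TPM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), ablated minus control and in either direction. P-values were adjusted by Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 is called passing. Intervals are 95% intervals from the same fit. Scores, permutations, correlations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

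Before the data were examined, 25 gene lists were fixed: pan-neuronal, transmitter and neuronal subtype, synaptic release and excitability, enteric glia and Schwann cell (the 4 main lists), neurotrophic factors, axon guidance, nerve injury, smooth muscle, interstitial cells of Cajal and PDGFRA-positive cells, macrophage and monocyte, acute inflammation and neutrophil, interferon response, T, B and plasma cell, mast cell, extracellular matrix and fibroblast activation, colonic epithelium, enteroendocrine cell, cell cycle, endothelium, mesothelium, adipocyte, skeletal muscle, immediate early and heat shock, erythrocyte, and posterior Hox. Each was tested with camera in limma at its preset correlation of 0.01, adjusted over the lists. Its score, the mean over tested members of the centred log2 values, was compared by exact permutation over all 792 splits of the libraries, for which the smallest possible p is 0.00126. Member counts are given adjusted over all genes and over the list alone. Lists of tuft cell genes, of goblet cell members and of glia-restricted members were added after the data were seen and appear only in the closing section.

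Genes named by rule are Actl6b and Hbegf, the 10 called genes with the largest log2 fold change in each direction (mean of at least 1 TPM in either group, all ablated libraries on the same side of the control mean, predicted and unnamed models left out), and up to 4 called members of each list with the smallest p, or up to 2 where none passed. Other list members were named after their values were seen, to show members that did not pass or that speak for another cell type. Some genes that these rules name are not reported here. Correlations between list scores were computed within the 7 ablated libraries only, with exact permutation of the pairings and adjustment over 7 relations.

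Alternatives changed the added constant (1 and 0.1), the minimum (none, and 1 TPM), the scaling (median of ratios, quantile), the variance model (no trend, robust, a weight per library), the covariates (smooth muscle, epithelium and sex-linked scores, library number as block), the list test (estimated correlation, fry) and the libraries (each left out in turn). After the data were seen, voom on the recovered reads, the shallowest library of each group left out and the mitochondrial share as a covariate were added. The libraries were also split in 100 ways into groups of the same sizes (seed 23), the real split included. The library numbers were checked as pairs by the correlation of same-numbered libraries after removing group means, which was 0.00935, 0.359, -0.269, 0.203 and 0.162 for numbers 1 to 5, so the numbers were not treated as pairs.

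The pipeline was tested on simulated data. Of 100 genes changed 2-fold 75 were called, of 99 tested genes changed 4-fold 96 were called, and 8 unchanged genes were called among 16249 run. With nothing changed, 0 of 16232 genes and 0 of 25 lists were called. The simulated genes were drawn independently, without the structure shared among real libraries or the correlation between list members. The simulated runs therefore do not measure how often genes or lists are falsely called in the real data. Whole reads were recovered exactly for 99.99% of simulated genes with at least 20 reads.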

Results

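Gene expression was measured by RNA sequencing of full-thickness mouse colon taken at the place where diphtheria toxin had been injected into the muscle wall. The study removed enteric neurons with the toxin, and its title places the work in the regrowth of these neurons after birth and in the part glia play. Mice of the ablated group (n = 7 libraries) carried BAF53b-Cre together with an inducible diphtheria toxin receptor at the Rosa26 locus, so that cells with a history of Cre expression become sensitive to the toxin. Littermates labelled Cre-negative, in which the receptor is not expressed, formed the control group (n = 5 libraries). Both groups underwent the same laparotomy and received the same toxin with India ink to mark the site, so the comparison is between toxin with and without its receptor. The labels give neither the time between toxin and dissection nor the sex of the animals. Ddx3y, a gene on the Y chromosome, was present in all 12 libraries, at 24.4 to 36.0 TPM (transcripts scaled to length and library).

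The values are TPM made by the authors, and 13.4 to 26.9 M reads per library were recovered from them, with means of 20.7 ± 3.08 M in control and 21.9 ± 4.26 M in ablated. Ablated 1 was the shallowest library. Mitochondrial transcripts took 18.7% of its reads, against 3.56 to 10.4% in the other 11 libraries, and it lay at 85.2 on the first principal component (40.05% of the variance), where the next library, ablated 6, lay at 44.5. The group means of the mitochondrial share were 7.85 ± 1.84% in control and 7.66 ± 5.43% in ablated. Below, levels are mean TPM ± SD over the 5 control and 7 ablated libraries, fold is the ratio of the group means, and log2 fold changes are on the log2(TPM + 0.5) scale, which understates the change of genes of low level. The labels number the libraries within each group without saying whether each came from its own mouse, so p-values measure the spread between these libraries. Adjusted p are from limma unless another test is named.

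The first question was how far the marked neurons were lost. Actl6b encodes BAF53b, the subunit of a chromatin remodelling complex that neurons use and the gene whose promoter drives Cre here (gene ID 83766, chromosome 5, 137553517 to 137569582 in mm10). It stood at 0.599, 1.25, 1.43, 0.617 and 0.960 TPM in the 5 control libraries and at 0.750, 0.429, 0.155, 0.507, 0.698, 0.225 and 0.363 TPM in the 7 ablated ones. The means were 0.971 ± 0.372 and 0.447 ± 0.224, a log2 fold change of -0.63 (95% interval -1.10 to -0.17) that did not pass the adjustment over all genes (adjusted p = 0.222). Only 93 reads in control and 55 in ablated lay behind these values, and the 10 nearest tested genes on the chromosome, 5 on each side, had a median log2 fold change of 0.45. Hbegf, the mouse form of the gene whose product the toxin binds in sensitive species, was at 11.8 ± 3.63 in control and 11.3 ± 3.36 in ablated (adjusted p = 0.980).

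Other neuronal transcripts were far lower in the ablated colon. Calb2, which encodes the calcium-binding protein calretinin of many enteric neurons, fell from 24.4 ± 10.1 in control (n = 5) to 0.537 ± 0.537 in ablated (n = 7), 45.6-fold. Htr3a, a subunit of the serotonin-gated ion channel, fell 27.0-fold from 8.94 ± 3.66 to 0.331 ± 0.249, and Vip, the neuropeptide of inhibitory motor neurons and secretomotor neurons, fell 7.83-fold from 84.7 ± 28.3 to 10.8 ± 9.26. Uchl1, the neuronal ubiquitin hydrolase PGP9.5, fell 6.03-fold from 41.8 ± 15.5 to 6.93 ± 2.56, and Ret, the receptor through which GDNF acts on enteric neurons, fell 4.74-fold from 3.29 ± 0.992 to 0.694 ± 0.204. For each of these 5 genes every ablated library lay below every control library.

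Over all genes, 231 of the 16164 tested passed an adjusted p of 0.05, of which 68 were higher and 163 lower in ablated. The groups did not overlap for 209 of the 231, and 466 of all genes tested (2.88%) had groups that did not overlap, against 0.253% by chance. With an absolute log2 fold change of at least 1 in addition, 154 genes remained, 29 higher and 125 lower. The other genes among the 10 with the largest falls were Prph, the intermediate filament peripherin (13.8-fold, adjusted p = 0.000706), the neuropeptide Nmu (15.4-fold, adjusted p = 0.000791), the translation factor Eef1a2 of neurons and muscle (12.2-fold, adjusted p = 0.00067), Stmn3, a stathmin that acts on microtubules (10.9-fold, adjusted p = 0.000194), the ATP-gated channel P2rx2 (15.5-fold, adjusted p = 0.000739), the neuropeptide Grp (6.60-fold, adjusted p = 0.00819) and the mucosal pentraxin Mptx1. Mptx1 is not a neuronal gene in the lists used here: it fell 4.32-fold from 9104 ± 725 to 2107 ± 2529 with an adjusted p of 0.0476, and leaving out any of the 5 control libraries or ablated 2, 4, 6 or 7 raised that p to between 0.0800 and 0.128. The total was 128 without control 2, 137 without control 3, 349 with no minimum on low values, 628 with an epithelial score as a covariate, 1087 with the mitochondrial share as a covariate and 1092 with a weight per library, where the excess turned to the higher side (654 higher, 438 lower). The higher genes numbered 42, 23, 31, 41 and 40 without control 1 to control 5 in turn, 45 without ablated 4 or ablated 7, and 126 without ablated 1, and the lower genes 105 and 106 without control 2 and control 3.

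Lists of marker genes fixed beforehand were then compared. Of 30 pan-neuronal genes tested, 19 fell and none rose (0/24 up and down when adjusted over the list alone), and all 30 had a negative log2 fold change, with a median of -1.51. Beyond the genes above, Syt1, the calcium sensor of vesicle release, fell 11.05-fold from 4.35 ± 1.88 to 0.394 ± 0.157. The ablated means of the 19 that fell were 7.26% (Prph) to 32.8% (Stmn2) of control. Stmn2, a stathmin tied to axon growth, stood at 23.2 ± 5.72 against 7.61 ± 2.996. Thy1, a surface protein also carried by lymphocytes and fibroblasts, did not pass (22.05 against 21.1, adjusted p = 0.932), nor did the RNA-binding protein Celf5 or the microtubule protein Mapt. The list as a whole was lower than other genes by camera (adjusted p = 6.52e-45), and its score was 1.46 log2 units lower (exact permutation over all splits of the libraries, p = 0.00126, the smallest these can give).

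Of 23 genes tested for transmitters and neuronal subtypes, 12 fell and none rose (13 down and 1 up adjusted over the list alone), with a median of -1.41 (camera adjusted p = 3.16e-19). Markers of different enteric neuron classes were among them. The cholinergic genes Slc18a3, the vesicular acetylcholine transporter, fell 9.86-fold from 1.51 ± 0.439 to 0.153 ± 0.0912, and the choline transporter Slc5a7 also fell (1.13 against 0.0998, adjusted p = 0.00226). Penk and Tac1, which encode enkephalins and substance P, fell to 13.2 from 41.0 and to 31.3 from 69.5. Chat, the acetylcholine-synthesising enzyme, stood at 0.657 ± 0.282 and 0.568 ± 0.178 (adjusted p = 0.930). Nos1, the nitric oxide synthase of inhibitory motor neurons, lay below the minimum level; in a fit without that minimum it fell from 0.967 ± 0.399 to 0.0931 ± 0.0903 (adjusted p = 0.00252). Ddc and Slc6a4, which epithelial cells also express, were at 73.2 against 73.5 and at 14.6 against 14.9.

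The list for synaptic release and excitability split. Of its 31 tested genes 9 fell and none rose (12 down and 2 up adjusted over the list alone), the median was -0.44, and 9 members had a positive log2 fold change (camera adjusted p = 2.55e-11). Chrna3, a nicotinic receptor subunit of autonomic ganglia, fell 25.1-fold from 3.77 ± 1.90 to 0.150 ± 0.116. Syt4, Rab3c and Syn1, which take part in vesicle traffic, fell 7.87-fold, 6.26-fold and 4.00-fold. Vamp2, at 78.4 and 76.8, and Cplx2, at 4.68 and 4.45, did not pass, while Cplx1 of the same complexin family fell from 1.49 ± 0.409 to 0.318 ± 0.186 (adjusted p = 0.00537). Camera calls for these 3 neuronal lists held with an estimated correlation between genes, at adjusted p of 0.0160, 0.0160 and 0.0487, and no other list of the 25 held.

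**Figure D1:**
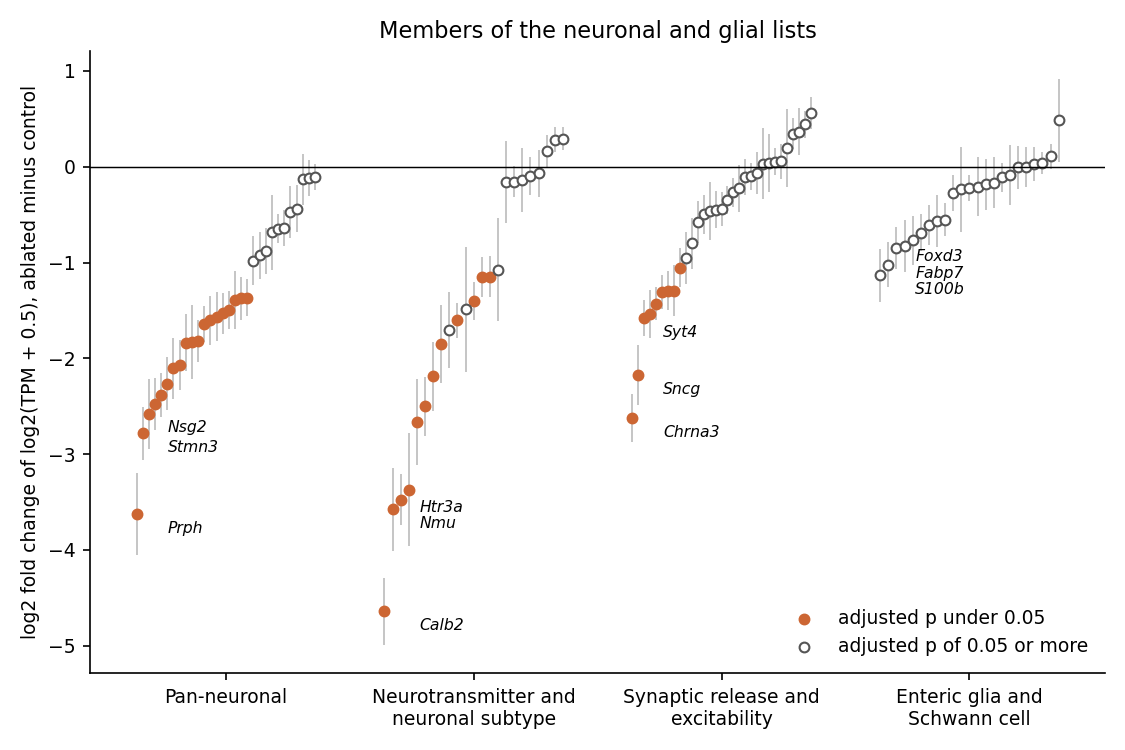
Log2 fold change of log2(TPM + 0.5), ablated (n = 7) minus control (n = 5), for each tested member of 4 gene lists, ordered within the list, with standard errors from limma as bars. Filled points passed an adjusted p of 0.05 over all genes tested: 19 of 30 pan-neuronal, 12 of 23 transmitter and subtype, 9 of 31 synaptic and 0 of 23 glial members, all on the lower side; the 3 lowest of each list are named.

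**Figure D2:**
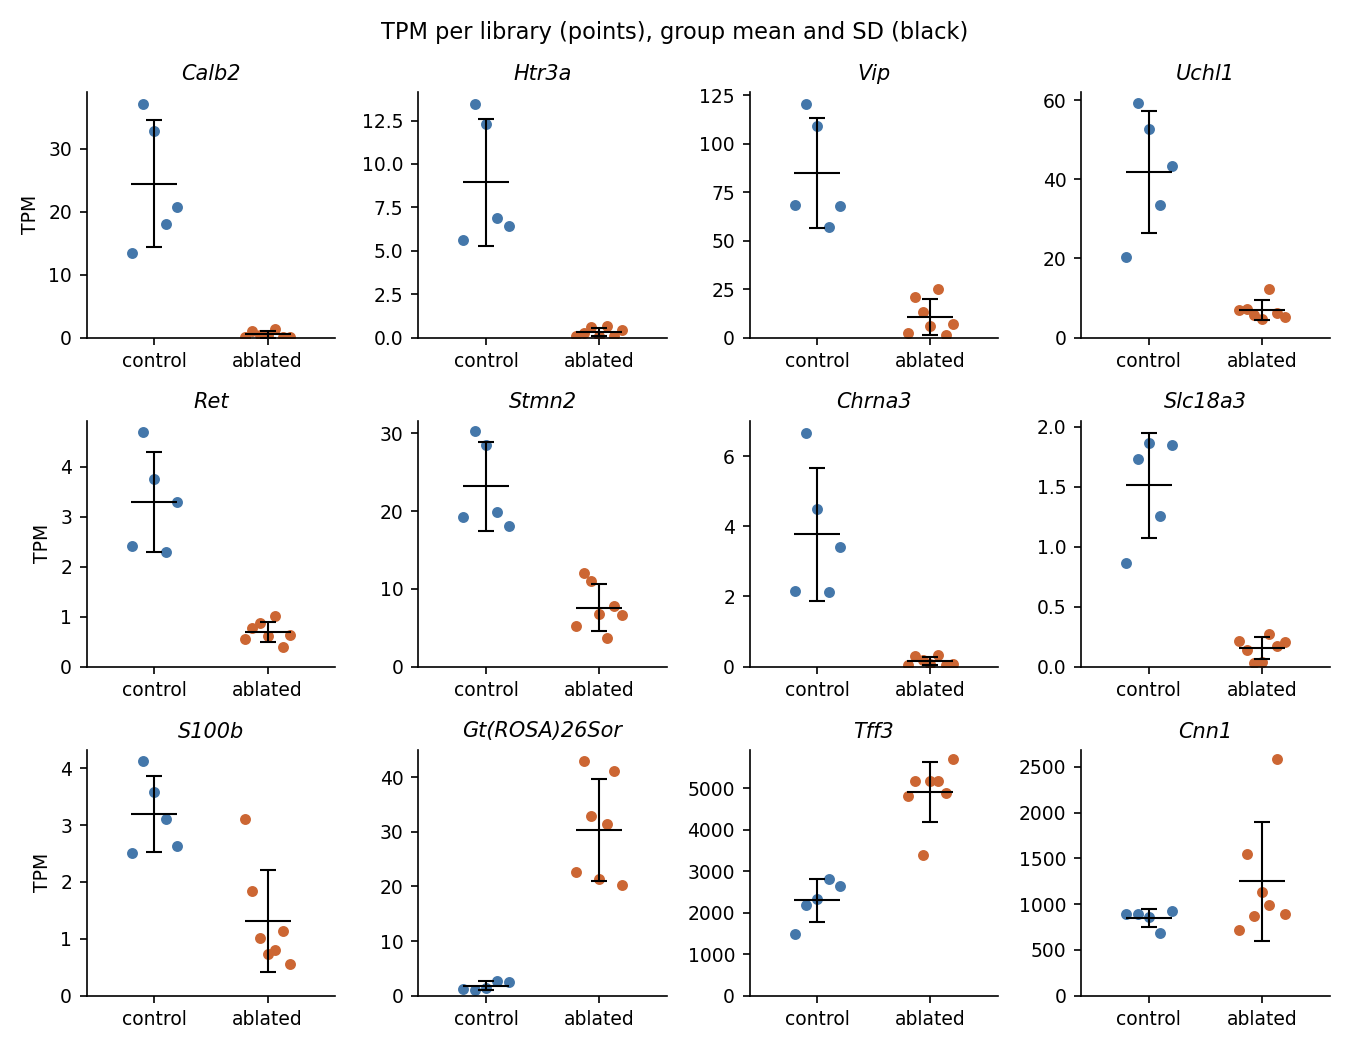
TPM of 12 genes in each control (blue, n = 5) and ablated library (orange, n = 7), with the group mean and SD in black on linear axes from 0. The ablated libraries lie below all control libraries for the 8 neuronal genes of the upper rows and above them for Gt(ROSA)26Sor and Tff3, while S100b and Cnn1 overlap.

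Glial transcripts differed less. None of the 23 genes tested for enteric glia and Schwann cells passed over all genes, while 8 fell when adjusted over the list alone; 19 had a negative log2 fold change and the median was -0.22. The calcium-binding glial protein S100b was at 3.19 ± 0.674 and 1.31 ± 0.895 (adjusted p = 0.0703), and the fatty acid-binding protein Fabp7 at 1.17 ± 0.413 and 0.340 ± 0.302 (adjusted p = 0.0536). Without ablated 1 the adjusted p of S100b was 0.00684, and without ablated 5 that of Fabp7 was 0.00927 (ranges over all alternatives 0.000989 to 0.330 and 0.00927 to 0.360). Sox10, the transcription factor of the glial lineage, stood at 2.65 and 2.08. The list was lower by camera (adjusted p = 8.36e-06; adjusted p = 0.0750 with an estimated correlation), and its score was 0.34 log2 units lower (exact permutation p = 0.00253, adjusted p = 0.0158).

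Lists for growth factors, axon guidance and nerve injury showed few calls. Among 19 neurotrophic factors and receptors, Ngfr, the p75 neurotrophin receptor of glia and neurons, fell 3.09-fold from 3.73 ± 1.30 to 1.21 ± 0.446 and none rose (2 down and 1 up adjusted over the list alone). The ligands themselves did not pass over all genes, with Gdnf at 1.45 against 2.004 and Bdnf at 0.373 against 3.06 (adjusted p = 0.163). Adjusted over the list alone, Bdnf was the 1 up (adjusted p = 0.0367). Of 33 axon guidance genes only the adhesion molecule Chl1 fell, from 1.68 ± 0.645 to 0.604 ± 0.243 (2 down and 2 up adjusted over the list alone), with an adjusted p of 0.0375; it did not pass without any one of the 5 controls or ablated 4, 6 or 7 (adjusted p of up to 0.123). Netrin, Slit and semaphorin genes did not pass over all genes. The 2 up adjusted over the list alone were Sema3b and Sema3c (both adjusted p = 0.0158). In the nerve injury list of 22, the 3 genes that fell were Stmn2, Gap43 (16.3 ± 5.55 to 5.50 ± 2.29) and Ngfr, all of which neurons or glia express without injury (6 down and 2 up adjusted over the list alone). The adjusted p of Gap43 was 0.0556 without control 2 and 0.0537 without control 3. Induced injury genes did not pass over all genes: Atf3 was at 31.4 and 37.3 and Sprr1a at 5.45 and 11.2. Olig1, Sox11 and Ecel1 of this list lay below the minimum level. In a fit without that minimum Olig1 rose from 0.00702 to 0.153 (adjusted p = 0.0198), both far under 0.5 TPM. Sox11 and Ecel1 did not pass in that fit (adjusted p = 0.586 and 0.812). By camera the adjusted p of the neurotrophic, guidance and injury lists were 0.543, 0.940 and 0.355.

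With predicted gene models left out, the largest rises in log2 fold change were those of Ermap and Gt(ROSA)26Sor. Ermap, which encodes an erythroid membrane protein (chromosome 4, 119175457 to 119190011), rose 74.9-fold from 0.241 ± 0.134 in control (n = 5) to 18.1 ± 5.76 in ablated (n = 7). Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus (chromosome 6, 113067428 to 113077333), rose 16.7-fold from 1.82 ± 0.780 to 30.3 ± 9.35. The lowest ablated library lay 18.2-fold above the highest control library for Ermap and 7.27-fold for Gt(ROSA)26Sor, and the groups differ in genotype by design. Apoc2, an activator of lipoprotein lipase, rose 5.37-fold from 10.2 ± 3.87 to 55.0 ± 32.3. Spink1, a secreted trypsin inhibitor, rose 3.32-fold from 491 ± 104 to 1632 ± 463, and the tight junction protein Cldn4 rose 2.69-fold from 51.0 ± 26.6 to 137 ± 52.3. Creb3l3, a transcription factor of lipid metabolism, rose 4.18-fold, the ferlin gene Fer1l6 3.55-fold, the mitochondrial creatine kinase gene Ckmt2 2.84-fold and the secretoglobin gene Scgb2b20 7.07-fold, the last from 0.538 ± 0.634. Cldn4 did not pass without control 1, 2, 3 or 4 or ablated 4, 5 or 7 (adjusted p of up to 0.126), nor did Apoc2 without control 1 or 2 (0.0598 and 0.0754), Fer1l6 without control 2 or 3 (0.0560 and 0.0505), or Scgb2b20 without control 2 (0.0634). In the fit on recovered reads the adjusted p of Scgb2b20 was 0.0706, with a range over all alternatives of 0.00288 to 0.277.

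Of 27 epithelial genes tested, 3 rose and none fell (5 up and 2 down adjusted over the list alone). The 3 are secreted by goblet cells into the mucus: Zg16 rose 2.53-fold from 4413 ± 1223 to 11146 ± 2572, Tff3 2.14-fold from 2298 ± 511 to 4909.7 ± 729 and Fcgbp 1.83-fold from 411 ± 46.6 to 751 ± 204. Other goblet cell members did not pass: Muc2, the main mucin, was at 998 and 1726 (adjusted p = 0.123), and Clca1, Agr2 and Spink4 had adjusted p of 0.684, 0.565 and 0.282. Also not passing was the general epithelial gene Epcam, at 1520.2 and 1377 (adjusted p = 0.722). The list did not pass camera (adjusted p = 0.0518), but passed without control 4 (0.0256), control 5 (0.0172), ablated 1 (0.0279), ablated 3 (0.0122) or ablated 6 (0.0226), within a range over all alternatives of 0.00117 to 0.995. Fcgbp had an adjusted p of 0.0389, and leaving out any library other than ablated 1 or ablated 3 ended its call (adjusted p of up to 0.140). Among 18 enteroendocrine genes, Tph1, the enzyme of serotonin synthesis in enterochromaffin cells, rose 1.97-fold from 5.95 ± 1.11 to 11.7 ± 1.64, and the calcium-binding protein Scgn fell 2.28-fold from 9.12 ± 2.71 to 4.01 ± 1.23 (1 up and 2 down adjusted over the list alone). Chga was at 73.8 and 85.0. Scgn did not pass without control 2, 3 or 4 or ablated 6 or 7 (adjusted p of up to 0.0969), and the enteroendocrine list did not pass camera (adjusted p = 0.825).

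Of 20 T, B and plasma cell genes, 19 had a negative log2 fold change with a median of -0.67, and none passed over all genes or adjusted over the list alone. Jchain, the joining chain of secreted IgA and IgM, was at 555 ± 113 and 219.6 ± 159 (adjusted p = 0.126, and 0.0454 without ablated 5), and the B-cell receptor component Cd79a at 14.1 ± 12.1 and 4.15 ± 3.95 (adjusted p = 0.174, and 0.0439 without ablated 3). Camera called the list lower (adjusted p = 4.13e-07; adjusted p = 0.543 with an estimated correlation), and the exact permutation of its score gave p = 0.0593. Outside the list and chosen after their values were seen, the light chain gene Iglc3 (111 ± 36.1 to 33.7 ± 23.4, adjusted p = 0.0476) and the plasma cell receptor Tnfrsf17 (4.15 ± 0.746 to 1.87 ± 0.681, adjusted p = 0.0407) fell.

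Of 28 genes for extracellular matrix and fibroblast activation, Col6a1, a chain of collagen VI, rose 1.58-fold from 30.6 ± 4.71 to 48.6 ± 6.65 and none fell (3 up adjusted over the list alone). Of the 28, 20 had a positive and 8 a negative log2 fold change, with a median of 0.39 (camera adjusted p = 4.85e-05; adjusted p = 0.635 with an estimated correlation), and camera gave 0.138 with a weight per library (2.95e-08 to 0.635 over all alternatives). Fibronectin, Fn1, was at 81.4 and 160 (adjusted p = 0.0668), and Col6a1 did not pass without control 2, 3 or 4 (0.0864, 0.0841 and 0.0546). The 11 tested skeletal muscle genes all had a positive log2 fold change and none passed over all genes (2 up adjusted over the list alone), with Tnnt3, a fast troponin T, at 6.42 ± 3.43 and 27.6 ± 27.1 and the actin Acta1 at 7.03 ± 4.17 and 16.2 ± 6.20. That list passed camera (adjusted p = 0.0149; adjusted p = 0.556 with an estimated correlation), but not without ablated 1 (0.173), and over all alternatives from 0.000205 to 0.556.

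Other cells of the wall showed no call as a list. For 22 smooth muscle genes the median log2 fold change was 0.04, with the contractile protein genes Actg2 at 1840.0 ± 351 and 3218 ± 1930.0 and Cnn1 at 850 ± 95.3 and 1247 ± 647. For 11 genes of interstitial cells of Cajal, the pacemaker cells, and of PDGFRA-positive cells it was -0.09 (1 up and 1 down adjusted over the list alone). The chloride channel Ano1 of the pacemaker cells was at 84.3 ± 10.6 and 126 ± 21.3 with an adjusted p of 0.0504, which was 0.0493 without ablated 2 and 0.0462 without ablated 3, and their transcription factor Etv1 was at 3.23 and 1.998. Medians were -0.05 for 24 macrophage and monocyte genes, where Mertk stood at 14.7 and 20.9 and Cd163 at 1.07 and 0.720, and -0.03 for 26 genes of acute inflammation and neutrophils, where Ptgs2 stood at 3.54 ± 1.81 and 11.2 ± 11.9 and Saa1 at 2647 and 3504. Camera adjusted p were 0.543, 0.635, 0.465 and 0.940 in that order. The smooth muscle list passed without ablated 1 (0.0136) and the macrophage list without ablated 3 (0.0185), with ranges over all alternatives of 0.00355 to 0.988 and 0.0185 to 0.995.

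The remaining 9 lists gave no camera call either. Interferon response genes (26 tested, camera adjusted p = 0.355) had a median of 0.00, with Psmb8 at 73.2 ± 25.2 and 42.8 ± 43.1 and Irf1 at 99.02 and 62.4; without ablated 3 the list passed on the lower side (8.82e-05), as did Psmb8 (0.00577) and Irf1 (0.0162), and the list also passed without control 3 (0.0391). Mast cell genes (6 tested, 0.355) had a median of -0.19, with Tpsb2 at 1.57 and 0.882, and passed without control 2 (0.0403). Cell cycle genes (22 tested, 0.465) had a median of 0.08, with Plk1 at 116 and 167, and passed without ablated 1 (0.0301). Medians were 0.14 for endothelium (16 tested, 0.635), 0.13 for mesothelium (9 tested, 0.543), -0.01 for adipocytes (11 tested, 0.825), 0.02 for immediate early and heat shock genes (17 tested, 0.635), 0.18 for erythrocytes (6 tested, 0.543) and -0.05 for posterior Hox genes (11 tested, 0.635). Apart from the erythrocyte list, their smallest p belonged to Erg (1.15 against 1.91), Msln (8.43 against 13.5), Plin4 (4.94 against 5.87), Hsph1 (36.6 against 18.6) and Hoxd11 (7.69 against 11.8), none of which passed. In the erythrocyte list 1 member fell and none rose, both over all genes and adjusted over the list alone, and in the other 8 lists no member passed either way. Median and mean differed in sign for the nerve injury (0.06 and -0.22), acute inflammation (-0.03 and 0.05), interferon (0.00 and -0.10), enteroendocrine (0.10 and -0.02), immediate early (0.02 and -0.05), erythrocyte (0.18 and -0.20) and posterior Hox lists (-0.05 and 0.07), and camera pointed down for the neurotrophic list, whose median was 0.05.

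**Figure D3:**
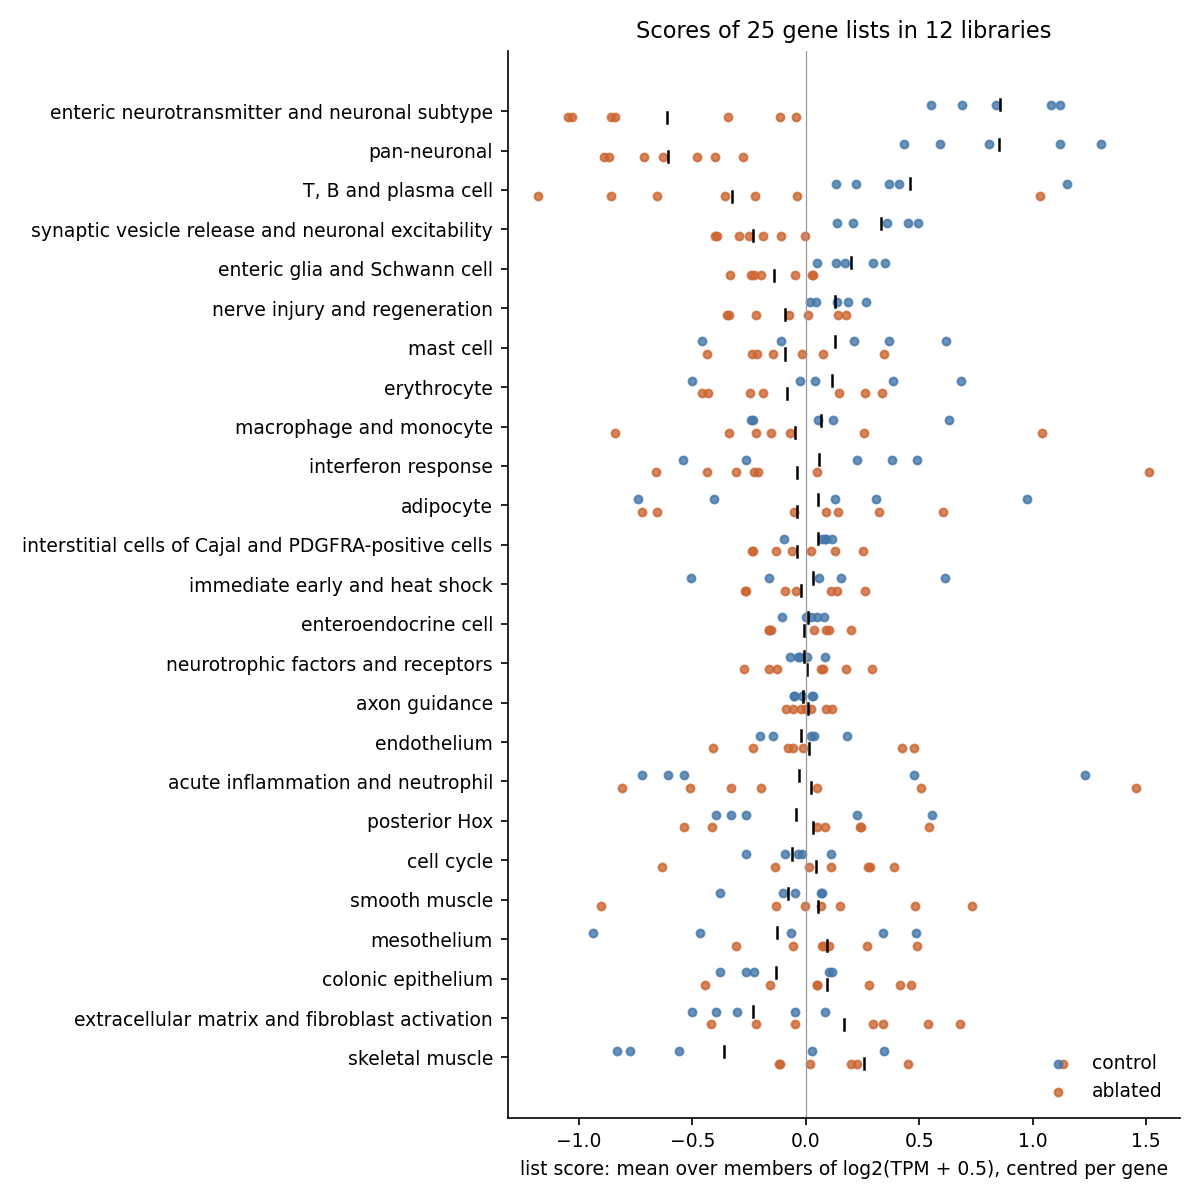
Score of each of 25 gene lists (mean over its tested members of log2(TPM + 0.5), centred per gene) in each control (blue, n = 5) and ablated library (orange, n = 7), with group means as black bars, ordered by the difference between the groups. The groups do not overlap for the 3 neuronal lists and the glial list, with pan-neuronal means of 0.85 in control and -0.61 in ablated, and they overlap for the other 21 lists.

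Within the 7 ablated libraries the pan-neuronal score was compared with 7 other list scores, to see whether libraries with fewer neuronal transcripts also differed elsewhere. Pearson's r was 0.788 for the transmitter and subtype list (exact permutation p = 0.0558), 0.833 for the synaptic list (p = 0.0240) and 0.809 for the glial list (p = 0.0403), with an adjusted p of 0.130 for each by permutation. Spearman's rho was 0.607, 0.821 and 0.714 (exact permutation p = 0.167, 0.0341 and 0.0881). For macrophages, acute inflammation, smooth muscle and epithelium r was 0.524, 0.0222, 0.141 and -0.164 (exact permutation p = 0.231, 0.967, 0.772 and 0.726) and rho 0.5, -0.214, 0.0714 and -0.143. None of the 7 relations passed the adjustment. Without ablated 2 and 4, the libraries farthest from the median, r was 0.724, 0.771, 0.750, 0.540, 0.529, -0.0388 and -0.0301 in the same order over 5 libraries.

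The authors' deposited table of their own edgeR comparison lists 306 genes with a false discovery rate under 0.05, 57 higher and 249 lower. Of these, 228 were tested here and 199 were called, all 199 in the same direction, 29 were tested and not called, and 78 lay below the minimum level used here. Another 32 genes were called here only. For Actl6b the authors' deposited table gives a log2 fold change of -1.17 with a false discovery rate of 0.336, and for Mptx1 one of -2.16 with a rate of 0.159.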

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

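The regroupings, the test of RNA quality on the run near Actl6b, that of extra copies of the stretch, that of tissue layers on the 5 separated genes and that of tuft cells were written down before their values were computed; the tests of a chance run, of a stretch of another strain, of genotype at engineered loci, the 3 tests on glia and that on goblet cells were chosen after the result was seen.

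A library was singled out where its distance from the next library, as a share of the range of its group, passed the limit that chance passes about 1 in 20 times. This was so in 18 of 198 groups of values, against 9.9 expected by chance. Among controls these were the reads of control 1 (0.806; 15.2 M, next 21.1), the interstitial cell score of control 5 (0.777; -0.10, next 0.07), the T, B and plasma cell score of control 4 (0.726; 1.15, next 0.41), Cnn1 in control 4 (0.721; 685 TPM, next 856) and Cd79a in control 4 (0.738; 35.0 TPM, next 13.3). In ablated 1 they were the share of reads in the top 10 genes (0.649; 20.1%, next 11.5%) and Dnaja1 (0.578; 25.03 TPM, next 39.9), and in ablated 2 Stmn3 (0.584; 1.68 TPM, next 0.878). In ablated 3 they were the interferon score (0.674; 1.51, next 0.05), Psmb8 (0.854; 139.6 TPM, next 36.5), Cd79a (0.753; 12.8 TPM, next 4.44) and Tff3 (0.612; 3392 TPM, next 4817). In ablated 5 they were Mptx1 (0.681; 7556 TPM, next 2602), Uchl1 (0.681; 12.4 TPM, next 7.16), Fabp7 (0.648; 0.981 TPM, next 0.419) and Ngfr (0.643; 2.12 TPM, next 1.25), and in ablated 6 Ptgs2 (0.659; 36.8 TPM, next 15.3) and Tnnt3 (0.708; 85.9 TPM, next 31.4).

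When the libraries were regrouped, 4 of 100 splits, the real one included, called as many genes as the 231 found. It was likewise 4 of 100 for the 68 higher genes and 4 of 100 for the 163 lower ones. The same other splits, which called 1477, 3101 and 3796 genes, reached all of these counts, so they are not separate results. A share of 4 in 100 lies just under 0.05 and would vary with the splits drawn. It therefore does not settle whether the number of calls comes from the grouping. The highest other split called 3796 genes in total, and the highest counts of other splits were 2955 higher and 2531 lower, while the median was 0. That split puts control 2, control 3, ablated 1, ablated 2 and ablated 6, the 5 libraries highest on the first principal component, on the same side, which points to structure among the samples that is not the group.

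Of the 10 tested genes from Pop7 to Nyap1 around Actl6b (chromosome 5, 137501438 to 137741607), 8 were higher and 1, Gnb2, was called (368 ± 40.8 to 551 ± 28.9 TPM, limma adjusted p = 0.00526); the ends of this stretch were chosen from its rises. With 3, 5 or 10 neighbours on each side of Actl6b instead, the median log2 fold change was 0.57, 0.45 and 0.18. Of all windows centred on a gene, that of Actl6b included, 0.0530%, 0.00667% and 3.65% had neighbours as far from 0. This window test was chosen after the rises were seen, and its narrower windows hold the genes that rose. These shares therefore cannot decide whether the run arose by chance. The exact permutation p of the score of the neighbours was 0.00126, 0.0253 and 0.218 at these widths. In every alternative the median of the 9 genes was 0.34 or more. Because the stretch was picked for its rises, that median cannot decide on differences in RNA quality. All 7 ablated libraries scored above every control over the 9 genes, by 0.0272 log2 units at the least, and over 3 neighbours per side, but not over 5 or 10. Extra copies of a stretch carried with the Cre transgene, which could add Actl6b reads in ablated, cannot be told apart from other causes, because the stretch was picked for its rises and the groups are the genotypes.

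Besides Ermap and Gt(ROSA)26Sor, 3 predicted genes (Gm14133, Gm1965 and Gm14719) had their lowest ablated library 4.76-fold to 27.1-fold above the highest control, while the next gene reached 1.58-fold; the 5 were chosen after their values were seen. Over the alternatives, with muscle, epithelial and mitochondrial covariates among them, the smallest log2 fold change of the 5 genes was 1.13. Because the genes were picked for their gap, a clearly positive value was likely beforehand. It therefore cannot decide on RNA quality or tissue layers as the cause. Of the 349 tested neighbours within 5 megabases of the 4 mapped genes 0.860% were called (95% binomial interval 0.178 to 2.49%), against 1.49% of all mapped genes, which argues only against a stretch of another strain that at least doubles the calls among neighbours; a stretch that changes the gene alone stays open, and Gm14719 has no mapped position. Genotype at the engineered loci, with Gt(ROSA)26Sor 7.27-fold above, cannot be told apart from a response to ablation with these labels.

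Glia-restricted members of the glial list had a score 0.63 lower (exact permutation p = 0.00126). Their fall was 0.83 log2 units smaller than that of the pan-neuronal list. The scale understates falls of low genes, and members of both lists under the minimum were left out. The difference therefore depends in part on level and cannot decide whether glia were lost in proportion to neurons. With a smooth muscle score as covariate the score of the glial list was 0.36 lower (exact permutation p = 0.00253) and camera gave an adjusted p of 6.68e-06 at its preset correlation (without the covariate, adjusted p = 0.0750 with an estimated correlation), which argues against another share of muscle. The restricted 12 members differed from the other 11 by -0.59, and transcripts of other cell types that hide part of the fall cannot be told apart from a fall of only some glial genes.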

How the results depend on the processing

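Of the alternatives, voom on the recovered reads, the shallowest library of each group left out and the mitochondrial share as a covariate were chosen after the data were seen. All 231 called genes kept their sign in each of the 28 other fits in which they were tested. The total was 349 with no minimum on low values (273 lower), where more genes are tested, 1092 with a weight per library (654 higher, 438 lower), 628 with the epithelial score as a covariate (287 higher, 341 lower) and 1087 with the mitochondrial share as a covariate (467 higher, 620 lower). The higher genes numbered 115 with the sex-linked score as a covariate. The cause was not tested for these changes. Leaving out 1 library at a time gave 128 to 328 genes in total, 23 to 126 higher and 105 to 202 lower.

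With the library number as a block the total was 84 (15 higher, 69 lower), of which 77 were among the 231, and 13 named genes lost their call. The numbers were not shown to pair libraries, and the cause was not tested.

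Actl6b was lower and did not pass in any of 27 alternatives, with log2 fold changes of -1.27 to -0.44 and adjusted p of 0.0689 to 0.638. It has no value under a minimum of 1 TPM, which it does not reach in enough libraries. Hbegf changed sign, from -0.04 to 0.00949 with the block and 0.00937 with the epithelial score, and to between -0.25 and 0.0714 with 1 library left out, without passing; the cause was not tested.

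Among 39 named genes that were called, 21 kept the call in every alternative, and 1005 of 1090 alternative values passed with none of the other sign. Calls were lost most often for Mptx1 (15 alternatives), Fcgbp (14), Chl1 (11), Cldn4 (8) and Scgn (5). Adjusted p over all alternatives ran from 0.00159 to 0.180 for Mptx1, 0.00802 to 0.140 for Fcgbp, 0.0163 to 0.198 for Chl1, 0.0101 to 0.126 for Cldn4, 0.00612 to 0.0969 for Scgn, 0.00276 to 0.329 for Col6a1, 0.00109 to 0.0754 for Apoc2, 0.00194 to 0.0560 for Fer1l6 and 0.00259 to 0.0556 for Gap43. Of 31 named genes not called, 11 passed in some alternative (37 of 866 values): the ranges were 0.00777 to 0.167 for Ano1, 0.0152 to 0.396 for Irf1, 0.00577 to 0.665 for Psmb8, 0.0265 to 0.363 for Jchain and 0.0439 to 0.592 for Cd79a.

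For the 4 main lists 119 of 120 alternatives passed. The exception was the glial list at 0.0750 with an estimated correlation, a setting that widens the null by the correlation between members. Apart from that setting and fry, all alternatives kept the preset correlation of 0.01 and so do not test it. Of 630 values for the other 21 lists, 601 stayed on the same side of the threshold, 10 lost a call and 19 gained one. Ranges were 8.82e-05 to 0.928 for the interferon list, 0.0403 to 0.860 for mast cells, 0.0301 to 0.995 for cell cycle and 2.09e-12 to 0.543 for T, B and plasma cells. The smooth muscle correlation went from r = 0.141 to -0.0388 without ablated 2 and 4.

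Depth limits low genes: Actl6b rests on 93 control and 55 ablated reads. Of simulated 2-fold changes 75 of 100 were called, but these were drawn from genes of all levels. That share therefore does not measure the limit for low genes.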

Other observations

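Among further genes, all chosen after their values were seen, several enteric neuron and glial genes outside the lists fell in ablated. Tlx2, a homeobox gene of enteric neurons, went from 1.61 ± 0.396 to 0.0621 ± 0.0723 TPM, Pirt from 3.78 ± 1.504 to 0.308 ± 0.186 and Pcp4 from 22.2 ± 8.05 to 4.56 ± 2.99. Gpr37l1 and Scn7a, which glia express, fell from 2.83 ± 0.683 to 0.669 ± 0.309 (limma adjusted p = 0.00284) and from 4.22 ± 1.11 to 1.47 ± 0.628 (adjusted p = 0.00759). Of epithelial genes, the sulfotransferase Sult1a1 fell from 498 ± 45.2 to 140.5 ± 34.1 (adjusted p = 2.93e-05) and the glycosyltransferase B4galnt2 from 138 ± 34.2 to 40.4 ± 18.02 (adjusted p = 0.00284). Sytl2 and Rab27a rose, Sytl2 from 12.8 ± 1.17 to 28.4 ± 6.86 and Rab27a from 19.0 ± 1.44 to 30.7 ± 3.56.

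On the Y chromosome the groups differed in opposite ways. Uba1y stood at 1.26 ± 0.321 TPM in control and 0.0586 ± 0.0932 in ablated (limma adjusted p = 0.000228), and Uty at 7.95 ± 0.666 and 11.4 ± 1.25 (adjusted p = 0.0389). Both were chosen after their values were seen, and no explanation was tested.

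A test for the source of Chat reads was written before its value was computed, and a test on goblet cell genes after the result was seen. Chat did not pass while Slc18a3 and Slc5a7 fell, and a candidate explanation is that tuft cells of the epithelium supply most of its reads. Within the 7 ablated libraries r of Chat with a score of 9 tuft cell genes was -0.126 (exact permutation p = 0.793), the tuft score differed by -0.04 between the groups (exact permutation p = 0.713), and no library had more than 35 Chat reads. The rule written beforehand counted a negative r against tuft cells, and r was negative. Given its exact permutation p of 0.793 and so few reads, that r carries little weight, and this source cannot be told apart from others.

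A larger share of epithelium in the ablated pieces could raise goblet cell transcripts. All 7 goblet cell members of the epithelial list had a positive log2 fold change and 3 passed, with a median of 0.75, against 0.13 for the other 20 members, and the scores differed by 0.75 (exact permutation p = 0.00379). The other members moved both ways without passing. Car1 rose from 1222 ± 436 to 2913 ± 978 TPM (limma adjusted p = 0.123). Muc3 fell from 4303 ± 681 to 2329 ± 698 TPM (limma adjusted p = 0.0625). A larger share of epithelium alone would raise both sets alike. The goblet set was formed after its 3 called members were seen and holds them, so the difference was in part built in. The scores therefore cannot decide whether a larger share of epithelium is the whole cause. A change within goblet cells remains a hypothesis found and tested on the same libraries.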
